A study of Papio hamadryas with 30 samples.

How the data were processed

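RNA of cortical bone (left femur midshaft, frozen and pulverised) and of PBMC was taken from the same 15 baboons, 14 females and 1 male, DNase treated, amplified and biotinylated, and hybridized to Illumina human bead arrays, per the labels' protocols. The 30 arrays lay on 4 slides, with both arrays of an animal on neighbouring positions of a slide. Bone always took one position of each pair and PBMC the other, so tissue and position cannot be told apart. The probes target human transcripts, so a sequence difference in the baboon can lower the signal of a probe.

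The deposited file of non-normalized values gives the mean bead intensity of each of 22184 probes on each array, per the file headers, with no further normalization. The same deposited file gives a detection p-value for each probe and array, per the file headers, made by comparing the probe with the array's negative controls. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. A deposited table of the series holds intensity values that are background-subtracted and normalized between arrays on a linear scale, as its values show (some below 0, and a rank correlation of 1 with the non-normalized signal of the same array). The method behind that table is not given in the sources used here, so it served only as an alternative, with values below 0 set to 0 and 16 added before log2. The table names 18168 distinct gene symbols. A further 32 probes, whose symbols a spreadsheet had turned into dates, were tested but not named.

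The non-normalized signals were background-corrected, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the detection p-values. A probe was kept for a tissue when its detection p was under 0.01 on at least 8 of 15 arrays of that tissue, for the tissue comparison when kept for either tissue, and for correlation across tissues when detected on at least 12 of 15 arrays of each. Detected probes per array ran from 6224 to 8469. The spread between animals is given as a standard error or SD beside the values.

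Bone was compared with PBMC over all 30 arrays with limma's linear model and moderated t test, with Benjamini-Hochberg adjustment at 0.05. The comparison of detected probes per array used all 32768 sign flips of the within-animal differences. Slopes on age were fitted in each tissue with a term for sex, and the difference of slopes on the bone minus PBMC values of each animal. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, when at least 5 genes were measured. The test was repeated with the correlation estimated from the data. A list's adjusted p is over all lists of the comparison, and over both tissues for age. Correlations across animals were tested with 100000 permutations in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), whose smallest p is 1e-05, and figures were drawn with matplotlib 3.10.9. A gene was taken to fall into separate groups when the same animals lay on each side of a gap of over 0.3 of the range in both tissues, a share chosen after a first look at the data.

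A gene is represented by its probe with the highest mean level over the 30 arrays. The genes named were set in advance: the 12 largest differences in each direction among those past the threshold with the same sign in 15 animals, up to 4 members of each described list with the smallest p, a short roll of bone, blood and muscle markers, the 8 smallest p of each age comparison, and the 15 highest and 3 lowest correlations across tissues. Among 478 genes with several tested probes, 28 had probes called in opposite directions. Where a gene was detected on under 8 arrays of the tissue where it was lower, its fold is given as "at least", with that tissue set on each array to no less than the lowest detected level of the array. List medians were also computed with such genes at this bound. Single detections lay mostly on the PBMC array of animal 5 (81 of 89 named genes) and the bone array of animal 6 (14 of 21), and extending the bound from genes with 0 detections to those under 8 was decided after the data were seen. ACTA1 was not analysed here, and a few other genes that this rule takes are not reported here.

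The labels state that both samples of a number come from the same animal, which pairs the arrays. As a check, the deviations of bone and PBMC from their tissue means had a mean correlation of 0.243 within animals, over 0.1 in 13 of 15. Both arrays of an animal were also neighbours on a slide, so this check cannot separate the animal from the array position. The tissue comparison, the age slope in bone, the list test between tissues and the correlation across tissues were tested on simulated data. Age slopes in PBMC, the difference of slopes, detected probes per array and the similarity within animals were not simulated. The tissue model recovered 52%, 90%, 98% and 100% of simulated differences of 0.5, 1, 2 and 4 log2 units. The age model, simulated with the spread of the bone arrays, recovered 0%, 0%, 34% and 94% of slopes of 0.02, 0.05, 0.1 and 0.2 log2 units per year. Slopes under 0.1 in bone would thus mostly be missed. The correlation test recovered 20%, 74%, 98% and 100% at true correlations of 0.6, 0.8, 0.9 and 0.95. False calls were 9, 2 and 7, and camera called the 1 shifted list of 20 and no other. The simulated genes varied independently of each other. These counts therefore do not give the rate of false calls where genes vary together, as in real lists.

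Alternatives were no background correction, scaling of arrays to a common median, the table of the series, no detection filter or a threshold of 0.05, animal or slide as a block, normalization within a tissue, leaving out each animal, the oldest animal, the male or the 2 animals farthest from the median age, rank of age, and Spearman in place of Pearson. Chosen after the data were seen were leaving out animals 5 and 6, the muscle and erythroid list means as covariates for age, and slide as a block for the lists with age. Cell proportions, genotypes and bone density were not used here.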

Results

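Transcript levels were measured in cortical bone and in peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of circulating blood) of 15 baboons (Papio hamadryas), an Old World monkey used here as a model of bone upkeep and turnover. Cortical bone is the dense outer shell of a long bone, and here came from the midshaft of the left femur. Each animal gave both samples, so the data hold 30 arrays, 15 of each tissue. The animals were 14 females and 1 male, aged 11.24 to 27.34 years with a median of 15.08 years. The arrays were Illumina bead arrays with probes designed on human transcripts, and 22184 probes were read on each. They lay on 4 slides, which held animals 1 to 4, 5 to 7, 8 to 11 and 12 to 15, with both arrays of an animal on the same slide. The number of arrays limits the precision of every value given here.

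Median raw signal per array ran from 51.4 to 61.3. Between 6224 and 8469 probes per array were detected above background. Arrays of PBMC resembled each other with r of 0.923 to 0.986, and arrays of bone with r of 0.822 to 0.979, both across probes, which are not independent replicates. No 2 arrays held identical values.

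The first question was how much of the bone transcriptome is also seen in blood cells. Cortical bone showed more detected probes than PBMC, 7452 ± 435 against 6927 ± 411 (mean ± SD, n = 15 each), and the count was higher in bone in 12 of 15 animals. The mean difference of 524.6 probes (SD 576) gave p = 0.00433 in a two-sided exact permutation of the tissue within animals. On at least 8 of 15 arrays, 7427 probes were detected in bone and 6876 in PBMC. Of the 8332 probes detected in either tissue, 5971 (71.7%) were detected in both, 1456 in bone alone and 905 in PBMC alone. Over the 5971 shared probes the mean levels of the tissues correlated with r = 0.808 and rho = 0.783, again across probes.

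Cortical bone and PBMC were then compared directly. The genes furthest above PBMC in bone were dominated by contractile and metabolic proteins of skeletal muscle. SLN, a regulator of the muscle calcium pump, lay at 14.18 on the log2 scale in bone and was at least 318-fold higher than in PBMC. MB, the oxygen-binding protein myoglobin, was at least 269-fold higher, the myosin light chain gene MYL1 at least 268-fold, the muscle creatine kinase gene CKM at least 287-fold and the fast troponin gene TNNC2 at least 223-fold. IGFBP5, an abundant binding protein for insulin-like growth factors in bone, was at least 231-fold higher. The rule also took MYL2 (at least 208-fold), the small heat shock protein gene CRYAB (at least 233-fold), the myosin heavy chain genes MYH7 (at least 263-fold) and MYH2 (at least 166-fold), MYBPC1 (at least 156-fold) and the filamin gene FLNC (at least 140-fold). All 12 genes were higher in bone in 15 of 15 animals, which the rule for naming required, with adjusted p of 1.37e-18 or smaller. Each was detected on 1 of 15 PBMC arrays, that of animal 5, so the folds are lower bounds and do not rank the genes.

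The genes furthest above bone in PBMC were those of T cells and cytotoxic lymphocytes. CCL5, a chemokine made by activated T and NK cells, differed by -5.73 in bone minus PBMC (SE 0.24), and lay at 11.67 in PBMC. The NK cell receptor genes KLRD1 (-5.20), KIR2DL3 (at least 27.6-fold lower) and KIR2DL4 (at least 17.4-fold lower) were also taken, with the interferon-inducible gene PYHIN1 at -5.20 and GZMH, a protease of cytotoxic granules, at -5.03. Genes of T cell identity and signalling were in the same range, with BCL11B at -5.14, CD6 at -4.87 and CD3G at least 24.8-fold lower. The chemoattractant receptor gene EBI2 was at least 27.6-fold lower and GPR18 at least 20.9-fold. These genes were lower in bone in 15 of 15 animals, again required by the rule, with adjusted p of 5.02e-16 or smaller. On the bone arrays KIR2DL4 was detected once, GPR18 on 2 arrays, KIR2DL3 on 3, CD3G on 4 and EBI2 on 6, and those with a log2 difference on 8 to 15.

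Across all 8332 probes, limma with Benjamini-Hochberg adjustment called 2634 higher and 4062 lower in bone, 6696 in all, and 1636 did not pass. With a difference of at least 2-fold, 1578 were higher and 1626 lower. In every one of the 15 animals the difference had the same sign for 1703 of the higher and 2532 of the lower probes. Within the 4 slides, each with 3 or 4 animals, limma called 5514, 2833, 5075 and 5480 probes, and between 98.8% and 99.9% of the 6696 calls kept their sign on each slide. With slide as a block 6801 probes were called. The split of calls leaned on the scaling: 39.3% of calls were higher in bone after quantile normalization and 29.3% after scaling arrays to a common median, where the median of all probes moved from -0.22 to -0.52. Of the called probes, 662 were detected on 0 PBMC arrays and 244 on 0 bone arrays, where a fold is only a lower bound.

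**Figure D1:**
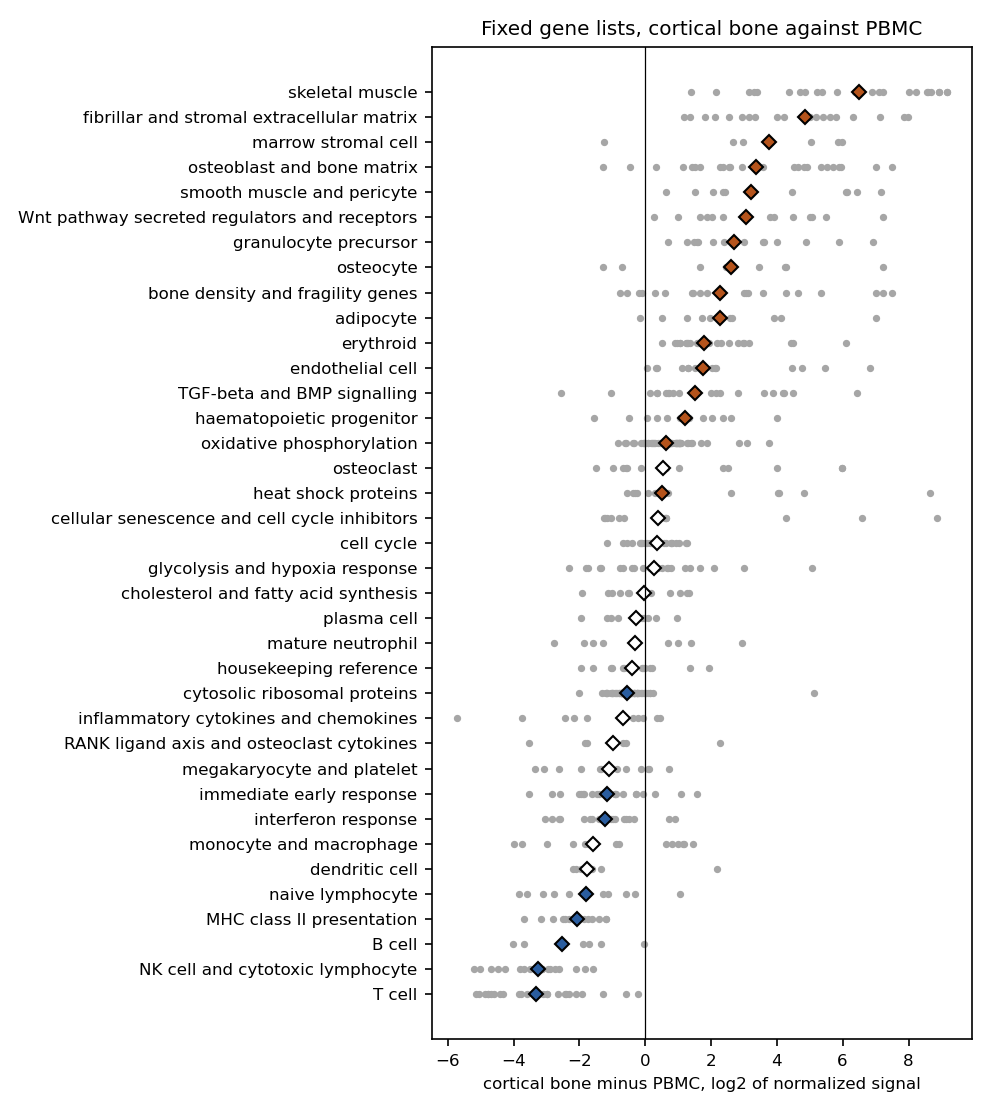
Difference between cortical bone and PBMC (log2, bone minus PBMC, n = 15 animals) for each measured gene (grey dots) of 37 gene lists, with diamonds for the list median, orange where the list was called higher in bone, blue where lower and white where not called. Bone, muscle, stromal, vessel and marrow lists lie to the right, led by skeletal muscle at a median of 6.49, and lymphocyte lists to the left, led by T cells at -3.33.

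Gene lists fixed in advance grouped these differences by cell type and pathway. Some lists share genes, such as SOST in the osteocyte, Wnt and bone density lists and CD34 in the endothelial and progenitor lists. Their calls are therefore not independent of each other. Of 37 lists tested with camera at a preset correlation, 16 were called higher and 8 lower in bone, and the same 24 lists were called without animals 5 and 6. Each of the 24 medians had the same sign within each of the 4 slides, and 24 lists were called with slide as a block. None was called with a correlation estimated from the data, where the smallest adjusted p was 0.0604. Genes detected on under 8 arrays of the lower tissue are given as at least a fold, and list medians also with these genes at that bound, where the 24 called lists all kept their sign. Members that went against a called list are named below, and were named after their values were seen. Counts of members adjusted over the list alone equalled those adjusted over all genes in every list except glycolysis, where 8 members rather than 7 were lower.

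Skeletal genes were high in cortical bone. In the osteoblast and bone matrix list 23 of 25 measured genes were higher and 2 lower, with a median of 3.37 (2.72 with genes at their bound, adjusted p = 8.80e-09, and adjusted p = 0.199 with an estimated correlation). Medians within slides ran from 3.19 to 3.68. Its members with the smallest p were the cadherin gene CDH11 (at least 23.2-fold), the mineralization inhibitor gene MGP (at least 29.8-fold), the osteoblast transcription factor gene DLX5 (at least 13.4-fold) and the collagen chaperone gene SERPINH1 (at least 13.7-fold). COL1A1, the main collagen of bone, was at least 60.7-fold higher, and BGLAP, which encodes osteocalcin, at least 51.6-fold, both higher in bone in 14 of 15 animals. The osteoblast transcription factor gene SP7 was at least 6.57-fold higher, ALPL, the alkaline phosphatase of mineralizing cells, differed by 2.95, and SPARC was at least 2.59-fold higher. BGLAP was detected on 3 PBMC arrays and ALPL on 14. The 2 lower members were the kinase gene BMP2K (-1.27) and the collagen-modifying gene CRTAP (-0.47). PBMC of animal 5 had a mean of 7.54 over this list, against 5.26 in the next highest PBMC array.

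Osteocytes, the cells embedded in mineralized bone, were represented by 9 measured genes, of which 7 were higher and 2 lower in bone (median 2.61, or 2.27 with genes at their bound, 2.36 to 2.96 within slides, adjusted p = 0.00288, and adjusted p = 0.171 with an estimated correlation). SOST, the Wnt inhibitor that osteocytes secrete, reached 12.40 in bone and was at least 86.5-fold higher. MEPE, a phosphoglycoprotein of bone matrix, was at least 9.31-fold higher, PDPN at least 9.41-fold and IRX5 at least 4.82-fold. The 2 lower members were the actin-capping gene CAPG (at least 2.09-fold) and the chaperone gene HYOU1 (-0.71), detected on 7 and 8 bone arrays. DMP1, RUNX2, TNFSF11 and the B cell gene MS4A1 were detected on 0 arrays and PHEX on 4 bone arrays, so none was tested.

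Osteoclast genes did not move as a group: 8 of 14 were higher, 5 lower and 1 did not pass (median 0.54, adjusted p = 0.147). Single members were far higher in bone, among them CA2 (at least 34.6-fold), the carbonic anhydrase that acidifies the resorption pit, the creatine kinase gene CKB (at least 7.99-fold), the matrix protease gene MMP9 (at least 44.7-fold) and CTSK, the collagen-degrading cathepsin (2.36, SE 0.25). ACP5, the tartrate-resistant phosphatase of osteoclasts, differed by 2.52 (SE 0.38). CA2 was detected on 4 PBMC arrays, MMP9 on 6 and CTSK and ACP5 on all 15. The osteoclast genes named are all among the 8 higher members, and the 5 lower ones are not named here. In the RANK ligand axis, 6 of 7 genes were lower and 1 higher (median -0.99, adjusted p = 0.210): TNFRSF11B, the decoy receptor that blocks osteoclast formation, was at least 3.07-fold higher, and FOS (-3.51), SPI1 (-1.78) and CSF1R (-1.83) were lower.

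Matrix and signalling lists of connective tissue followed the osteoblast list. All 21 fibrillar and stromal matrix genes were higher in bone (median 4.84, or 3.86 at the bound, 4.15 to 5.17 within slides, adjusted p = 1.90e-11, and adjusted p = 0.123 with an estimated correlation), including FBN1 (at least 14.5-fold), COL12A1 (at least 14.7-fold), FBLN2 (at least 22.4-fold) and the basement membrane collagen gene COL4A1 (at least 71.2-fold). All 16 Wnt regulators and receptors were higher (median 3.05, or 2.02 at the bound, 3.07 to 3.27 within slides, adjusted p = 8.99e-09, and adjusted p = 0.0604 with an estimated correlation), with the receptor gene FZD4 at least 15.2-fold, WISP2 at least 6.97-fold and LGR4 at least 2.23-fold higher. For TGF-beta and BMP signalling, 17 of 20 were higher and 2 lower (median 1.51, or 0.86 at the bound, 1.34 to 1.85 within slides, adjusted p = 8.27e-06, and adjusted p = 0.0869 with an estimated correlation). FST, which binds activins, was at least 8.40-fold higher, BMP4 at least 9.39-fold, TGFB3 at least 4.28-fold and LTBP2 at least 2.53-fold. ID2, an inhibitor of DNA-binding proteins that lymphocytes also use, was at least 4.67-fold lower, and the secreted matrix gene TGFBI was lower by a difference of -1.05. Among genes tied to bone density and fragility, 20 of 25 were higher and 1 lower (median 2.29, or 1.44 at the bound, 2.07 to 2.53 within slides, adjusted p = 3.18e-07, and adjusted p = 0.0807 with an estimated correlation), with ARHGAP1, a GTPase regulator, as the lower member (-0.78), the oestrogen receptor gene ESR1 at least 5.15-fold and LRP5 at least 1.66-fold higher. ID2 was detected on 5 bone arrays and TGFBI and ARHGAP1 on all 15.

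Other stromal and vessel lists were higher too. Marrow stromal cell genes were higher in 7 of 8 and lower in 1 (median 3.78, or 3.17 at the bound, 3.51 to 4.49 within slides, adjusted p = 0.000613, and adjusted p = 0.123 with an estimated correlation), led by PDGFRB (at least 31.9-fold), EBF3 (at least 18.1-fold) and CXCL12 (at least 27.4-fold), the chemokine that holds blood stem cells in marrow, while the cytokine gene IL7 was at least 1.21-fold lower. Adipocyte genes were higher in 9 of 10 (median 2.27, or 1.34 at the bound, 1.97 to 2.63 within slides, adjusted p = 0.000288, and adjusted p = 0.123 with an estimated correlation), with the adipocyte regulator gene PPARG at least 12-fold, the fatty acid carrier gene FABP4 at least 99.7-fold and CIDEA at least 6.84-fold higher. Endothelial genes were higher in 13 of 14 (median 1.77, or 1.08 at the bound, 1.60 to 1.93 within slides, adjusted p = 2.53e-06, and adjusted p = 0.0604 with an estimated correlation), among them CDH5 (at least 12.9-fold), the water channel gene AQP1 (at least 59.1-fold) and SOX18 (at least 14.2-fold). All 11 smooth muscle and pericyte genes were higher (median 3.22, or 2.68 at the bound, 2.80 to 3.58 within slides, adjusted p = 2.79e-07, and adjusted p = 0.0604 with an estimated correlation), such as TPM1 (6.15) and MYH11 (at least 54.2-fold), detected on 15 and 7 PBMC arrays. Of the chondrocyte list 4 genes were measured, too few for a list test, and all 4 were higher, with COMP at least 60.1-fold and CHAD at least 14.0-fold higher. COMP was detected on 6 PBMC arrays, PPARG on 2 and FABP4 on 3. On the PBMC array of animal 5 these lists stood above the other PBMC arrays as the osteoblast list did, at 6.74 against 5.07 for marrow stroma and 6.17 against 4.84 for Wnt regulators.

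Skeletal muscle was the list furthest above PBMC. All 25 measured genes were higher in bone, with a median of 6.49 (5.45 with genes at their bound, adjusted p = 3.38e-13, and adjusted p = 0.180 with an estimated correlation). Medians within slides ran from 5.34 to 7.34. The mean of the list differed widely between bone samples, 11.4 ± 1.17 (SD, n = 15), from 8.71 in animal 6 to 12.8 in animal 8. Over the 15 bone arrays it fell as the osteoblast list mean rose (r = -0.764, p = 0.000860, adjusted 0.00473; rho = -0.711, p = 0.00422, adjusted 0.0232; r = -0.757 without the 2 farthest animals, and -0.782 with slide means removed; permutation tests in a family of 22 relations). The first principal component of the bone arrays, with 44.3% of their variance, followed the muscle list mean with an absolute r of 0.904 and rho of 0.971 (permutation p = 2e-05 and 1e-05, the second being the smallest they can give).

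**Figure D2:**
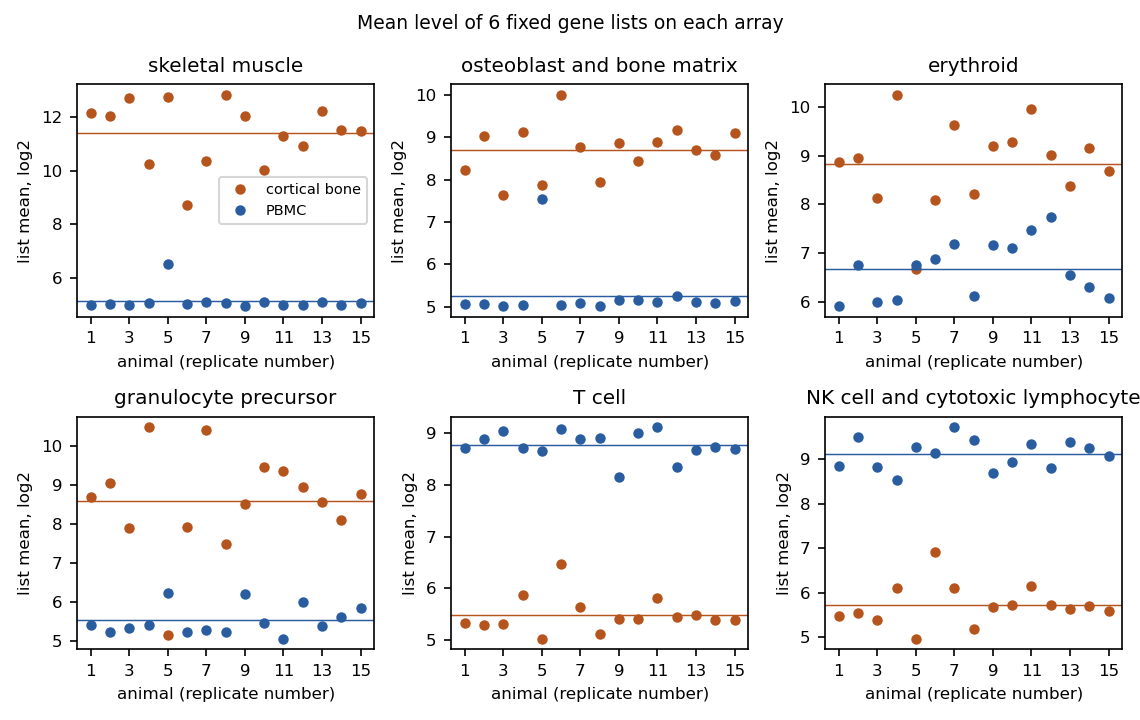
Mean log2 level of 6 gene lists on each of the 30 arrays, with a short line at the mean of each tissue (n = 15). The skeletal muscle mean in bone spans 8.71 to 12.8, and the PBMC array of animal 5 lies above the other PBMC arrays for osteoblast genes, at 7.54 against at most 5.26.

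Blood-forming cells of the marrow were visible in bone. All 25 erythroid genes were higher (median 1.77, or 1.36 at the bound, 1.09 to 2.44 within slides, adjusted p = 2.24e-06, and adjusted p = 0.277 with an estimated correlation), including ERAF (at least 39.8-fold), a chaperone of alpha haemoglobin, and the red cell membrane genes ANK1 (at least 5.18-fold) and XK (at least 2.57-fold). HBB, the beta globin gene, was bright in both tissues, at 14.63 in bone and 13.58 in PBMC. Granulocyte precursor genes were higher in 13 of 14 (median 2.70, or 1.72 at the bound, 2.06 to 3.40 within slides, adjusted p = 0.000109, and adjusted p = 0.355 with an estimated correlation), with the eosinophil granule gene PRG2 at least 61.7-fold higher, MPO, the peroxidase of azurophil granules, at 5.88 (SE 0.50) and CTSG at least 8.14-fold higher. On PBMC arrays ERAF was detected 4 times, ANK1 6 and MPO 8. Haematopoietic progenitor genes were higher in 11 of 14 and lower in 2 (median 1.21, or 0.73 at the bound, 0.79 to 1.42 within slides, adjusted p = 0.00586, and adjusted p = 0.126 with an estimated correlation), with the homeobox gene HOXA9, detected on 2 PBMC arrays, at least 10.3-fold higher and SOX4, detected on 6, at least 5.52-fold. The lower members were the tubulin regulator gene STMN1 (at least 2.42-fold, detected on 5 bone arrays) and the surrogate light chain gene IGLL1 (at least 1.11-fold), which precursor B cells use. The bone array of animal 5 had the lowest means of the 15 for erythroid genes (6.68, tissue mean 8.83) and for granulocyte precursors (5.16, tissue mean 8.60).

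Lymphocyte genes were lower in bone. All 25 T cell genes were lower (median -3.33, or -2.84 at the bound, adjusted p = 4.13e-10, and adjusted p = 0.0869 with an estimated correlation), with CD40LG at least 5.10-fold lower, SIT1 at least 3.69-fold, the signalling kinase gene ZAP70 at least 15.0-fold and CD3E, part of the T cell receptor complex, at least 2.93-fold. All 18 NK and cytotoxic genes were lower (median -3.25, or -2.81 at the bound, -3.51 to -3.06 within slides, adjusted p = 1.32e-07, and adjusted p = 0.126 with an estimated correlation), among them the granzyme genes GZMM (at least 10.5-fold) and GZMB (-4.48) and FASLG (at least 4.47-fold). Of 9 B cell genes 8 were lower (median -2.52, or -1.60 at the bound, -2.92 to -2.07 within slides, adjusted p = 0.00103, and adjusted p = 0.226 with an estimated correlation), with CD79B at -2.52 and CD79A at least 3.04-fold lower. Naive lymphocyte genes were lower in 9 of 10 and higher in 1 (median -1.80, or -1.32 at the bound, -1.89 to -1.67 within slides, adjusted p = 0.0131, and adjusted p = 0.226 with an estimated correlation), with LEF1 at -3.58 and IL7R at least 9.78-fold lower, while the actin crosslinking gene ACTN1 was higher (1.07). On the bone arrays IL7R was detected on 2 arrays and GZMB, CD79B and LEF1 on all 15. Within slides the T cell median ran from -3.70 to -3.16. Bone of animal 6 had the highest T cell mean of the bone arrays (6.47, next 5.87) and the highest NK mean (6.91, next 6.15).

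Antigen presentation and response programmes were lower in bone as well. All 13 MHC class II genes were lower (median -2.06, -2.67 to -1.36 within slides, adjusted p = 0.00186, and adjusted p = 0.199 with an estimated correlation), with HLA-DOB at -3.68, HLA-DRA at -2.31 and the regulator gene RFX5 at least 2.30-fold lower. Interferon response genes were lower in 17 of 20 and higher in 2 (median -1.22, or -1.005 at the bound, -1.33 to -1.03 within slides, adjusted p = 0.00396, and adjusted p = 0.421 with an estimated correlation), with LY6E at -2.84 and OAS2 at -2.58, against the higher IFIT1 (0.72) and IFI27 (at least 1.36-fold, detected on 5 PBMC arrays). Immediate early genes, which rise within minutes of cell stimulation, were lower in 18 of 22 and higher in 2 (median -1.15, -1.42 to -0.89 within slides, adjusted p = 0.0138, and adjusted p = 0.421 with an estimated correlation), with ZFP36 at -2.60, KLF6 at -1.94 and KLF2 at -1.60, against the higher IER3 (1.58), which protects cells from apoptosis, and the stress-responsive gene ATF3 (1.09). Monocyte and macrophage genes went both ways, 11 lower and 6 higher of 17 (median -1.57, or -1.25 at the bound, adjusted p = 0.307): CD86 (-3.75), CX3CR1 (at least 11.7-fold), FCN1 (-2.99) and CD14 (at least 2.37-fold) were lower, while the 6 higher ones were FOLR2, VSIG4, MS4A6A and the complement genes C1QA, C1QB and C1QC, which resident macrophages make. On the bone arrays CD14 and RFX5 were detected on 2 arrays, OAS2 on 8, HLA-DOB on 10, CD86 on 12 and FCN1 on 14.

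Of the metabolic and housekeeping lists, oxidative phosphorylation was higher in bone in 43 of 60 genes and lower in 3 (median 0.63, or 0.61 at the bound, 0.54 to 0.83 within slides, adjusted p = 1.76e-05, and adjusted p = 0.444 with an estimated correlation). COX7A1, a muscle isoform of a respiratory chain subunit, was at least 7.90-fold higher, COX4I2 at least 3.19-fold, and NDUFS4 differed by 1.41, while the respiratory chain genes NDUFV3 (-0.83), COX6A1 (-0.61) and COX7C (-0.59) were lower. Its mean over the bone arrays followed the muscle list mean (r = 0.916, p = 1e-05, the smallest the permutations can give, adjusted 0.000110; rho = 0.986, p = 1e-05, adjusted 0.000220; r = 0.906 without the 2 farthest animals and 0.953 with slide means removed, family of 22). Cytosolic ribosomal protein genes were lower in 38 of 52 and higher in 2 (median -0.55, or -0.52 at the bound, -0.63 to -0.41 within slides, adjusted p = 0.00396, and adjusted p = 0.460 with an estimated correlation), with RPL29 at least 1.39-fold lower and RPL13A at -2.01, while RPL3L, a paralogue used in striated muscle, was at least 15.8-fold higher and RPS27L, a stress-induced paralogue, was higher by 0.22. Heat shock proteins were higher in 7 of 12 and lower in 3 (median 0.51, 0.42 to 0.66 within slides, adjusted p = 0.0281, and adjusted p = 0.418 with an estimated correlation), with CRYAB, which is abundant in muscle, the collagen chaperone gene SERPINH1, HSPB1 (at least 12.3-fold, detected on 2 PBMC arrays) and HSPA1B (4.03) furthest up. The chaperone genes HSPA8 (-0.55), DNAJB1 (-0.36) and HSPH1 (-0.31) were lower. With scaling to a common median the median over all genes was -0.51 instead of -0.20, and the medians were 0.23 for oxidative phosphorylation, -0.91 for ribosomal proteins and 0.05 for heat shock proteins.

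The remaining lists were measured without a call. Plasma cell genes had 4 of 11 lower and 2 higher (median -0.27, adjusted p = 0.629), dendritic cell genes 5 of 6 lower and 1 higher (-1.77, or -1.37 at the bound, 0.166), and megakaryocyte and platelet genes 8 of 12 lower and 1 higher (-1.10, or -0.98 at the bound, 0.307). Mature neutrophil genes had 4 of 8 lower and 3 higher, with a median of -0.30 (-0.28 at the bound) although the list test pointed up (adjusted p = 0.879). Cell cycle genes had 9 of 25 higher and 4 lower (0.35, or 0.21 at the bound, 0.196), and glycolysis and hypoxia genes 10 of 22 higher and 7 lower (0.28, or 0.04 at the bound, 0.357); both medians were below 0 with scaling to a common median, at -0.02 and -0.18. Inflammatory cytokine genes had 6 of 11 lower and 1 higher (-0.68, or -0.48 at the bound, 0.0856), cholesterol and fatty acid synthesis 6 of 13 lower and 4 higher (-0.04, 0.858), senescence genes 7 of 14 higher and 6 lower (0.38, 0.360), and housekeeping reference genes 9 of 17 lower and 3 higher (-0.40, 0.360).

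The next comparison asked which transcripts changed with age over the span of 11.24 to 27.34 years. Age was spread unevenly over the slides, numbered here in the order of their animals. Ages ran from 11.24 to 19.16 years on slide 1 and from 16.66 to 18.26 on slide 2. On slide 3 they ran from 12.06 to 15.08 and on slide 4 from 14.46 to 27.34. The main slopes held a term for sex but none for slide, so they do not fully separate age from slide. No gene passed the adjusted threshold in either tissue. In bone the lowest p belonged to SESN1, a stress-responsive regulator of nutrient signalling, at -0.183 log2 units per year (SE 0.031, adjusted p = 0.208). The genes that came next in bone had slopes of 0.130 (KIAA0644), 0.131 (LAMC3, a laminin chain), 0.101 (EPHA2, an ephrin receptor), 0.101 (BMP2, a bone-forming growth factor) and 0.112 log2 units per year (FAM32A), and of -0.102 (SMG1) and -0.0820 (DCUN1D4), with adjusted p from 0.211 to 0.310. In PBMC the slopes were -0.0619 for the leukocyte adhesion gene ICAM3 (adjusted p = 0.698), 0.0623 for FAM32A, 0.0481 for ZNF688, -0.133 for SESN1, -0.0561 for BSG, 0.0667 for C9orf50, -0.0469 for the chaperone gene HSP90AB1 and -0.0596 for AVEN, all with adjusted p = 0.699 after ICAM3.

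SESN1 and FAM32A were among the 8 lowest p in both tissues. SESN1 was detected on 13 bone and 11 PBMC arrays, and its level in bone followed age with r = -0.849 (p = 7e-05, adjusted 0.000384) and rho = -0.854 (p = 8e-05, adjusted 0.000640), and r = -0.763 without the 2 oldest animals, whose ages lay farthest from the median. In PBMC its r was -0.737 (p = 0.00299, adjusted 0.00478), rho -0.611 (p = 0.0171, adjusted 0.0205) and r -0.632 without those animals. FAM32A followed age in bone with r = 0.808 (p = 0.000720, adjusted 0.00144), rho = 0.821 (p = 0.000370, adjusted 0.00152) and r = 0.670 without the 2 animals. In PBMC its r was 0.799 (p = 0.000460, adjusted 0.00100), rho 0.632 (p = 0.0135, adjusted 0.0180) and r 0.590 without them. These permutation p-values were adjusted over 24 relations of genes already picked for a low p, so they do not replace the test over all probes. With slide as a block the slopes per year were -0.205 and -0.133 for SESN1 and 0.0968 and 0.0566 for FAM32A in bone and PBMC.

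**Figure D3:**
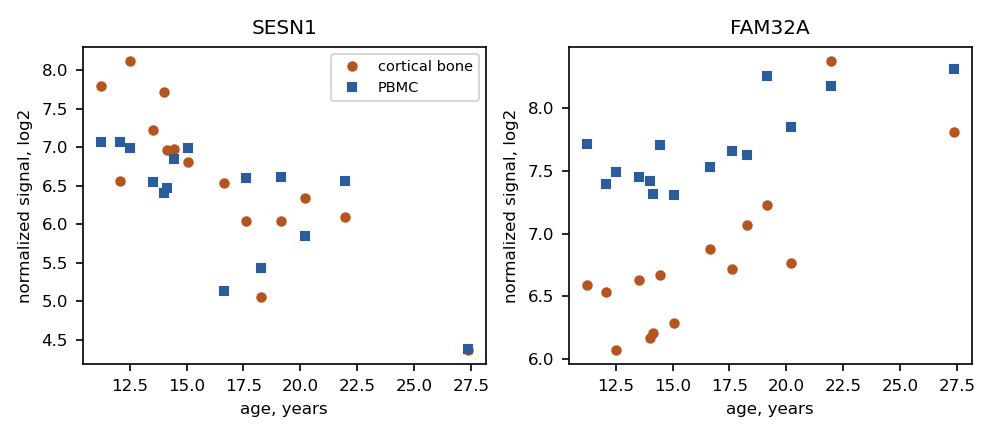
Normalized log2 level of SESN1 and FAM32A by age in years, with 1 point per animal in cortical bone and in PBMC (n = 15 each). The slope in bone is -0.183 log2 units per year for SESN1 and 0.112 for FAM32A, and neither passed adjustment over all probes.

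In bone, limma called 0 of 7427 probes with age, with 785 at an unadjusted p under 0.05 where 371 would come from chance if probes were independent; 17 of 100 permutations of age gave at least as many, so chance is not excluded. For PBMC 0 of 6876 were called, with 463 at an unadjusted p under 0.05, against 344 for independent probes, and 34 of 100 permutations gave at least as many. The slope in bone minus the slope in PBMC gave 0 of 5971, with 80 at an unadjusted p under 0.05 (299 for independent probes), and the lowest p belonged to FAM84B (-0.146), PDE1B (0.0685), PRPF8 (0.0709), EXOC7 (0.0860), PTGS1 (0.0995), FAM133B (-0.0573), PHGDH (0.0747) and NUP153 (-0.0866), each with adjusted p = 0.999. SESN1 in bone did pass in some settings, with adjusted p from 0.000879 to 0.994 over 28 alternatives: 0.00795 with scaling to a common median, 0.00186 with the muscle list mean as a covariate, 0.000879 with the muscle and erythroid list means, and 0.0412 without animal 6. FAM84B passed with slide as a block (-0.258, adjusted p = 0.00939), where its adjusted p ran from 0.00939 to 0.999993 over 26 alternatives. The slopes with slide as a block are pooled within slides.

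Fixed gene lists gave 3 calls with age among 63 tests. In bone, 23 of 25 osteoblast and bone matrix genes had rising slopes, with a median of 0.0412 log2 units per year (adjusted p = 0.0348, and adjusted p = 0.956 with an estimated correlation). Also in bone, 46 of 60 oxidative phosphorylation genes had falling slopes, with a median of -0.0136 (adjusted p = 0.0348, and adjusted p = 0.956 with an estimated correlation). In PBMC, all 8 measured heat shock genes had falling slopes, with a median of -0.0170 (adjusted p = 0.0348, and adjusted p = 0.956 with an estimated correlation). Adjusted over the list alone, 0, 0 and 1 members passed, and adjusted over all genes 0 passed in each list. None of the 3 was called without animals 5 and 6, where the median slopes were 0.0369, -0.0103 and -0.0176 (adjusted p = 0.0635, 0.0833 and 0.0635). With the muscle list mean as a covariate in bone the osteoblast median was 0.0364 (adjusted p = 0.147) and the oxidative phosphorylation median -0.00400 (adjusted p = 0.368), while the PBMC list, whose own fit held no muscle term, had adjusted p = 0.0559. With scaling to a common median the osteoblast list was called with a median of 0.0231 (adjusted p = 7.26e-05), and the other 2 were not, with medians of -0.0261 and -0.0349 (adjusted p = 0.0871 for each). Over 7 alternatives the adjusted p ran from 7.26e-05, 0.00132 and 0.00853 to 0.956. With slide as a block 23 of the 63 tests were called, these 3 among them with medians of 0.0429, -0.0265 and -0.0271 (adjusted p = 0.0106, 0.00132 and 0.00853).

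No list mean passed with age in the family of 22 relations. In bone 20 of 25 skeletal muscle genes had falling slopes, with a median of -0.0208 (adjusted p = 0.363, and 0.0144 with slide as a block). The muscle list mean had r = -0.190 with age (p = 0.498, adjusted 0.547). For the osteoblast list in bone r was 0.376 (p = 0.169, adjusted 0.286; rho = 0.436, p = 0.107, adjusted 0.181; r = 0.442 without the 2 oldest animals and 0.262 with slide means removed). For the heat shock list in PBMC r was -0.222 (p = 0.419, adjusted 0.512; rho = -0.125, p = 0.657, adjusted 0.761; r = -0.109 without those animals and -0.201 with slide means removed). In PBMC 10 of 11 erythroid genes had falling slopes, with a median of -0.0554 (adjusted p = 0.0791, 0.956 with an estimated correlation and 2.38e-05 with slide as a block). The erythroid list mean had r = -0.241 with age (p = 0.394, adjusted 0.509; rho = -0.025, p = 0.934, adjusted 0.995; r = 0.0489 without those animals and -0.463 with slide means removed). Of 12 megakaryocyte and platelet genes 9 had falling slopes, with a median of -0.0520 (adjusted p = 0.310, 0.956 with an estimated correlation and 7.34e-06 with slide as a block), and the list mean had r = -0.341 (p = 0.215, adjusted 0.330; rho = -0.25, p = 0.368, adjusted 0.476; r = -0.181 without those animals and -0.508 with slide means removed).

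Finally, each transcript was asked whether its level in blood cells followed its level in bone of the same animal. For several genes the animals fell into separate groups that were the same in both tissues. PEX5, a receptor for import into peroxisomes, was low in animals 1, 2, 8 and 12, with means of 5.69 in PBMC and 5.62 in bone against 9.05 and 9.39 in the others. EIF1, a translation initiation factor, was high in animals 2, 3, 5 and 6, at 11.03 in PBMC and 11.47 in bone against 5.95 and 5.83. The low groups of PEX5 and EIF1 lay among the lowest detected levels of the arrays, 5.09 to 5.98. Levels are those of a single probe per gene. A sequence difference under that probe cannot be told apart from a level of the gene. LEMD2, of the inner nuclear membrane, was low in animals 3, 5, 10, 13 and 14 (6.66 and 6.06 against 8.66 and 8.18), NDUFB7 in animals 4 and 8 (6.05 and 6.39 against 9.18 and 9.81) and PRPF31, a splicing factor, in animals 1, 14 and 15 (7.73 and 7.23 against 9.14 and 8.44). HSD17B11 was low in 7 animals, KARS in 8 and SET in 12. No pooled r is given for these 8 genes. Within the larger group r was 0.895 for PEX5, -0.460 for EIF1, 0.778 for LEMD2, 0.825 for NDUFB7, 0.571 for PRPF31, 0.201 for HSD17B11, -0.161 for KARS and 0.552 for SET, as descriptions without a test.

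HLA-E and MRPS26 did not meet the rule for such groups. In PBMC and bone the largest gap was 0.186 and 0.248 of the range for HLA-E, and 0.284 and 0.249 for MRPS26. The MRPS26 gap in PBMC lay just under the 0.3 chosen after a first look, so its r may rest in part on a gap between animals. HLA-E, an MHC class I gene that inhibits NK cells, ran from 10.01 to 13.44 in PBMC and from 6.84 to 11.37 in bone, with r = 0.920 (p = 1e-05, the smallest the permutations can give, adjusted 0.00385), rho = 0.946 (p = 1e-05, adjusted 0.00770) and r = 0.882 without the 2 farthest animals. For MRPS26, a mitochondrial ribosomal protein, r was 0.945 (p = 1e-05, adjusted 0.00385), rho 0.861 (p = 9e-05, adjusted 0.0299) and r 0.904 without 2 animals. With slide means removed r was 0.920 and 0.923, with adjusted p of 0.0838 and 0.279. For the tRNA synthetase gene EPRS the gap passed the threshold in bone but not in PBMC. Animals 3 and 14 lay lowest in both tissues (5.69 in PBMC and 5.82 in bone against 7.44 and 7.37), and r was 0.821 over the other 13, as a description, with no pooled r given. In 4 genes a single animal stood apart in both tissues, and the relation without 2 animals was weaker: BTBD2 (animal 2, r = 0.532), GNL3 (animal 5, r = 0.154, not called at adjusted p = 0.131), PSAP (animal 8, the male, r = 0.464) and PPP1R11 (animal 14, r = 0.766).

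EGR2, an immediate early transcription factor, was the one called gene whose level in bone was lower where its level in PBMC was higher (r = -0.809, p = 0.000260, adjusted 0.0219; rho = -0.707, p = 0.00375, adjusted 0.118; r = -0.758 without 2 animals; -0.784 with slide means removed). Its adjusted p ran from 0.00829 to 0.440 over 24 alternatives, and it was not called without animal 6 (0.0974), without animal 10 (0.0525) or without animals 5 and 6 (0.182). HYLS1 (r = -0.764, p = 0.00151, adjusted 0.0532; rho = -0.771, p = 0.00116, adjusted 0.0691; r = -0.584 without 2 animals) and CHD8 (r = -0.746, p = 0.00133, adjusted 0.0501; rho = -0.661, p = 0.00857, adjusted 0.170; r = -0.538 without 2 animals) were not called, with adjusted p from 0.0522 to 0.339 and from 0.0346 to 0.933 over 25 alternatives each. CHD8 passed without animal 3 (0.0346) and without animal 15 (0.0349). EGR2 is a member of the immediate early list, so the mean of that list is not separate from it. The list mean went in opposite directions in the tissues (r = -0.616, p = 0.0144, adjusted 0.0452, family of 22). Its rho was -0.529 (p = 0.0463, adjusted 0.102), and its r was -0.682 without 2 animals and -0.562 with slide means removed. For the MHC class II list r was -0.620 (p = 0.0128, adjusted 0.0452; rho = -0.450, p = 0.0949, adjusted 0.174) but -0.207 without 2 animals.

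**Figure D4:**
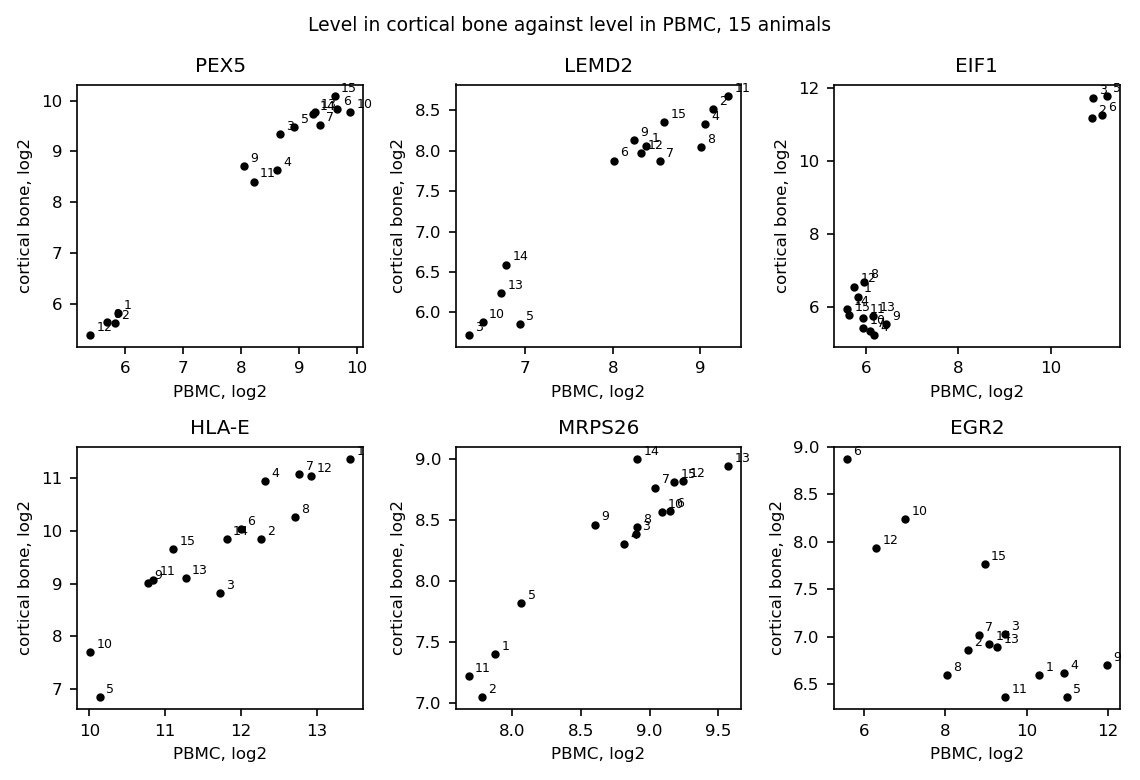
Normalized log2 level in cortical bone against PBMC of the same animal for PEX5, LEMD2, EIF1, HLA-E, MRPS26 and EGR2, with points numbered by animal (n = 15). PEX5, LEMD2 and EIF1 form separate groups holding the same animals in both tissues. HLA-E and MRPS26 rise (r = 0.920 and 0.945) without meeting the rule for groups, and EGR2 falls (r = -0.809). The largest gap of MRPS26 in PBMC, 0.284 of the range, lies just under the threshold of 0.3.

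Over the 5390 probes detected on at least 12 of 15 arrays of each tissue, permutation of the animals with Benjamini-Hochberg adjustment called 142, of which 141 had a positive r and 1 a negative r. The median r over all probes was 0.193, and 884 probes had an unadjusted p under 0.05, 832 of them positive. Among the 142, 12 showed separate groups, 14 had a single animal apart and 116 showed neither, and 107 of those 116 kept an unadjusted p under 0.05 without the 2 farthest animals. With slide means removed and shuffles held within slides 0 of 5390 were called, while 107 of the 142 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0838. The median r of the 142 was 0.812 before (quartiles 0.776 and 0.877) and 0.783 after (0.669 and 0.882), against 0.182 and 0.0877 for the other probes. Holding the shuffles within slides ended all the calls without removing the slide means, and with the means removed and free shuffles 81 of the 142 were kept. The count also moved to 38 with scaling to a common median, to 51 without animals 5 and 6, to 51 by Spearman (45 of them among the 142) and to between 77 and 194 on leaving out 1 animal.

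At the level of whole arrays, the deviations of an animal's bone from the tissue mean resembled those of its own PBMC. The mean correlation within animals was 0.243 (SD 0.142, from -0.0378 to 0.504, n = 15), against -0.0177 between different animals (permutation p = 1e-05, one-sided, the smallest they can give). Between different animals of the same slide it was 0.0818 and between slides -0.0426. Removing slide means left 0.164 within animals (p = 7e-05). Of the 15 bone arrays, 8 resembled the PBMC array of their own animal most. As both arrays of an animal were neighbours on a slide, animal and array position cannot be told apart in this similarity.

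A PBMC array and a bone array carried transcripts of the other tissue. Over 319 probes seen only in bone, PBMC of animal 5 held 9.10% of the median bone signal, against -0.0385% to 0.0582% in the other PBMC arrays, and 161 of these probes were detected on it. Over 33 probes seen only in PBMC, bone of animal 6 held 12.4% of the median PBMC signal, against 0.941% to 3.89% in the other bone arrays.

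**Figure D5:**
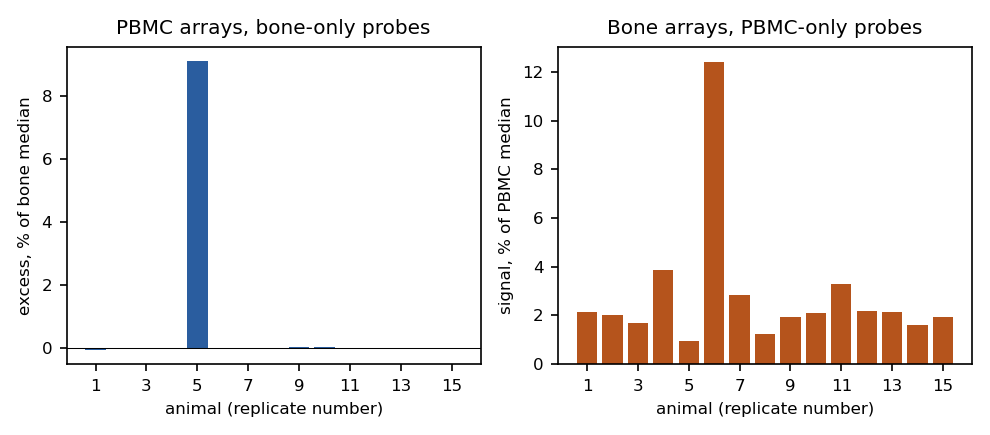
Share of the other tissue's signal on each array, by animal: PBMC arrays over 319 bone probes (left, percent of the median bone signal) and bone arrays over 33 PBMC probes (right, percent of the median PBMC signal). PBMC of animal 5 stands at 9.10% where the other PBMC arrays are at 0.0582% or less, and bone of animal 6 at 12.4% where the other bone arrays lie from 0.941% to 3.89%. The probes were chosen to be low in the other arrays, with PBMC of animal 5 and bone of animal 6 exempt from that choice.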

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

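The tests of RNA of animals 5 and 6 in each other's samples (except the test of PBMC RNA in bone of animal 6), of muscle tissue taken with the bone and of slide differences alone were chosen after the result was seen. The standard error set beside the thresholds for pairs of probes, the random groupings of animals, and the separate removal of slide means and of free shuffles were also added after the values were seen.

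RPS4Y1, a gene of the Y chromosome, was detected on the bone array of 1 female, animal 12, at a log2 level of 6.26 (detection p = 0.00141, 2.13% of the male's signal), while the next highest female stood at 4.46 and the male at 11.48. It drew attention as a signal where no female should carry the gene, and in PBMC it was detected in 0 females.

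PBMC of animal 5 carried bone transcripts and bone of animal 6 carried lymphocyte transcripts. The excess in PBMC of animal 5 followed the bone profile of animal 6 with r = 0.974 (next highest 0.813, animal 10) and that of its own bone with r = 0.434, which argues against bone RNA of animal 5 itself. An excess of 9.10% of the median bone signal argues against an exchange of whole samples. In bone of animal 6 the lymphocyte signal followed PBMC of animal 5 with r = 0.877 (next highest 0.552, animal 14; its own PBMC 0.0540), as written down before that value was seen, and the 2 values are consistent with a small exchange of RNA between these samples, which shared a slide. PBMC of animal 5 and bone of animal 6 lay on neighbouring positions of that slide. At which step such an exchange arose was not tested, and no biological explanation was tested.

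Skeletal muscle genes were high in bone of all 15 animals. The 25 genes varied together over the bone arrays with a median pairwise r of 0.899, which is consistent with a varying share of muscle tissue in the bone samples. Osteocytes as the main source of this variation would make the muscle and osteocyte lists rise together. Their r of -0.649 (p = 0.00989, adjusted 0.0435, with rho = -0.579, p = 0.0264, adjusted 0.0829, and -0.577 without 2 animals) lay under the bound of 0.2 written beforehand. It argues against osteocytes as the main source, although rho did not pass as a negative relation. Levels on a scale normalized within each array can push lists in opposite directions, and the osteoblast (-0.764) and T cell (-0.843) lists fell too. The negative sign thus cannot decide whether osteocytes express some of these genes, and does not give the share of muscle. No other biological explanation was tested.

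For 142 probes the level in PBMC tracked the level in bone of the same animal. Sequence differences under single probes and a level of the whole gene that differs between animals cannot be told apart: in 5 pairs of a called probe with another probe of its gene the median r was 0.208, under the threshold of 0.3 written beforehand for the first, but with a standard error of 0.141, while 165 genes without a called probe had a median of 0.438. Slide differences alone are argued against by pairing the animals anew within their slides, which called at most 13 probes over 99 pairings (median 0). New pairings also part arrays that lay side by side, so they do not separate the animal from the neighbouring positions of its arrays. The median r of the 142 was 0.812 before and 0.783 after slide means were removed. As these probes were picked for a high r in the same data, that median is no separate evidence. Whether slide differences shared by both arrays of an animal add to it stays open: 0 of the 142 were called with slide means removed, which met the condition written beforehand, but holding the shuffles within slides ended the calls by itself and 20 random groupings kept a median of 3 (from 0 to 27), so that count decides nothing, while the median r lay just under the 0.788 to 0.837 of the random groupings. Genotypes, which could separate the first 2 explanations, were not used here.

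Other assignments of the samples bear on chance. With the tissue swapped within animals, 1 of 100 assignments, the real one, gave as many as 6696 probes. This is the smallest share that 100 assignments can give, and it argues against chance. The highest other gave 5289 and had turned only 3 animals. With other pairings of the animals, 1 of 100, the real one, gave as many as 142 probes, and the highest other gave 3. That argues against chance there too, with the same limit of 1 in 100. For age, 17 of 100 permutations gave at least the 785 slopes of bone at an unadjusted p under 0.05 (highest other 2207) and 34 of 100 at least the 463 of PBMC (highest other 1493), so chance cannot be excluded. Permutations with several times the real count point to a structure of the samples that is shared by many probes.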

How the results depend on the processing

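Leaving out animals 5 and 6, the muscle and erythroid covariates, and slide as a block for the lists with age were chosen after the data were seen. Of the summary results under all alternatives, 221 stayed within 1.5 times of their value or on their side of the threshold and 29 moved. Of the single genes and lists, 2088 kept their side of the threshold, 94 lost their call, 7 gained one and 0 reversed. A change of sign counted as reversed only where a call was made in at least 1 setting. Changes of sign among uncalled values are therefore within the 2088. Left out of these counts are 6 and 48 values for age without the male, whom the sex term already sets apart, so that they equal the values with all animals by design. With animal as a block (pairing) 6857 probes differed between bone and PBMC, and the block changed the call of no named gene or list. Probe counts between tissues moved in 3 cases: 1069 lower by at least 2-fold without background correction, and 10618 different and 6788 lower without the detection filter, which tests more probes. The cause of the first was not tested. Leaving out each animal gave 6587 to 6668 different probes (2583 to 2632 higher, 3995 to 4076 lower; by at least 2-fold 1560 to 1591 and 1586 to 1676). With an estimated correlation 0 of 37 lists between tissues and 0 of 63 with age were called, in a test that widens the spread of a list whose genes vary together.

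For age in bone, 1 probe, SESN1, was called with median scaling, 1 with the muscle list and 1 with the muscle and erythroid lists as covariates, and 0 to 1 on leaving out each animal, the 1 being without animal 6. In PBMC and for the difference of slopes that range was 0 to 0, and slide as a block gave 1 probe for the difference, FAM84B. Lists with age numbered 5 with median scaling (1 of the 3 kept), 0 without animals 5 and 6, 0 with the muscle list as a covariate in bone and 23 with slide as a block. Probes correlated between tissues numbered 38 with median scaling, 308 without the filter, 75 when detected on all 30 arrays, 0 with slide means removed, 94 in females, 51 by Spearman and 51 without animals 5 and 6. Leaving out each animal gave 77 to 194, against 142 with all: 78 without animal 1, 77 without 2, 92 without 5, 82 without 6, 94 without 8, 82 without 11, 82 without 14 and 80 without 15. The cause of these moves was not tested. The similarity within animals stayed between 0.164 and 0.246. Signal over background limits dim genes, since 662 called probes were undetected on every PBMC array.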

Other observations

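In bone, the erythroid and granulocyte precursor lists varied together over the 15 animals (r = 0.921, p = 1e-05, the smallest the permutations can give, adjusted 0.000110; rho = 0.843, p = 0.000210, adjusted 0.00231; r = 0.782 without the 2 farthest animals and 0.928 with slide means removed; family of 22). The T cell list was lower in bone samples with a higher muscle list mean (r = -0.843, p = 0.000170, adjusted 0.00125, and rho = -0.793, p = 0.000670, adjusted 0.00491, with r = -0.823 without 2 animals and -0.828 with slide means removed). Its mean in bone, 5.49, lay among the lowest detected levels of the bone arrays (5.09 to 5.69). Of its 25 genes 14 were detected on under 8 bone arrays. Bone of animal 6, which carried PBMC transcripts, had the highest T cell mean (6.47) and the lowest muscle mean (8.71). Normalization within arrays can also set lists against each other. The adipocyte list had r = -0.0127 with the muscle list (p = 0.964, adjusted 0.996). Against the muscle list the erythroid list had r = -0.414 (adjusted p = 0.229) and rho = -0.55 (adjusted p = 0.0973). The granulocyte precursor list had r = -0.502 (adjusted p = 0.139) and rho = -0.679 (adjusted p = 0.0293). Without the 2 farthest animals r was -0.795 and -0.802. A shared fall with the muscle list was not separated from the relation of these 2 lists to each other. Neither the erythroid list (r = 0.208, p = 0.465, adjusted 0.538) nor the interferon list (r = 0.466, p = 0.0819, adjusted 0.180) in PBMC tracked its level in bone past the threshold.

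SESN1 and FAM32A, which had the same sign of slope with age in both tissues, were also compared between tissues after their values were seen. A slope of the same sign in both tissues by itself favours a positive r between them, and age was not taken out. FAM32A gave r = 0.842 (p = 0.000130; rho = 0.789, p = 0.000720; r = 0.844 without 2 animals and 0.779 with slide means removed), and SESN1 r = 0.720 (p = 0.00290; rho = 0.5, p = 0.0596; r = 0.625 without 2 animals and 0.543 with slide means removed), with no adjustment for the choice of these genes.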
